A study of Homo sapiens with 12 samples.

How the data were processed

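Poly-A RNA of 12 cultures was sequenced, 4 for each of 3 conditions: control, 2.5 µM acriflavine and 5 µM acriflavine. Per the labels' protocols, cells near confluence received fresh medium with drug or vehicle for 24 h. RNA was then purified and made into strand-marked mRNA libraries with a TruSeq Stranded kit, which were sequenced on a NextSeq500. The labels call the 4 libraries of a condition biological replicates.

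The authors deposited 1 table of whole-number counts of reads per Ensembl gene, which had not been normalized. Per the submitters' processing notes, reads were processed against GRCh37 with cutadapt 1.7.1, Bowtie2 2.2.4, STAR 2.4.1d, SAMtools 1.1, Cufflinks 2.1.1, bedtools 2.17.0, featureCounts 1.4.6 and edgeR 3.8.6. The notes give these names without their roles. The strand setting of the counting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. Reads of a gene and of its antisense partner can therefore not be told apart, and counts of near-identical copies (histones, processed pseudogenes and their parent genes) are uncertain.

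The table held 63152 genes, of which 32171 had 0 counts in every library, and 0 rows without a gene. Symbols and gene classes were looked up by Ensembl identifier in GENCODE 29, an annotation of GRCh38. A symbol was found for 51989 genes, which held 99.3% of the counts. No coordinates are given, because this annotation and the counts use different genome builds.

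Library totals ranged from 10733567 to 15116842 counts. Intervals and lower bounds drawn from counts use counts summed over the 4 libraries of a group. They cover counting error only and leave out variation between cultures. The libraries carried no molecular identifiers, so copies made in amplification could make these intervals too narrow. A gene with 0 counts in a group was set to a floor of 3 counts over the group. For the controls this is 0.0582 CPM of their summed totals, without TMM scaling.

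Genes were filtered with filterByExpr, which left 16839. Differences were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization and a quasi-likelihood fit (glmQLFit, robust, then glmQLFTest). The 12 libraries entered 1 fit with the 3 groups as its only terms and 9 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the genes tested, and 0.05 was the threshold. CPM values are those of edgeR's cpm function on the TMM-scaled library size and are given as mean ± SD. Log2 fold changes are given ± their absolute value divided by the square root of the quasi-likelihood F. This is called a standard error (SE) here. It can be too small for genes with few counts in a group. The biological coefficient of variation was 5.43%.

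Before the data were examined, 35 gene lists were fixed. They covered HIF targets outside glycolysis, glycolysis, epithelial junction and keratin genes, mesenchymal genes and EMT regulators, TGF-beta targets, hepatocyte secreted proteins, hepatocyte transcription factors and metabolism, AhR and xenobiotic response, and NRF2, p53, and ATF4 and CHOP targets. They also covered endoplasmic reticulum chaperones, cytosolic heat shock genes, DNA replication, mitosis, replication-dependent histones, DNA repair, topoisomerases, ribosome biogenesis, cytosolic ribosomal proteins, mitochondrially encoded mRNAs and nuclear-encoded oxidative phosphorylation. The others were cholesterol synthesis, fatty acid synthesis, interferon-stimulated genes, NF-kB genes, immediate early genes, WNT targets, apoptosis regulators, autophagy and lysosome, metallothioneins and zinc, and markers of fibroblasts, endothelial cells, blood cells and cholangiocytes. Of 843 entries, 833 were matched to a gene in the table. Lists with at least 5 tested members were tested with camera in limma 3.58.1, 2-sided, on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The 33 lists tested in a comparison were adjusted together.

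The genes named were also set by a rule fixed before the data were examined. It takes genes with a symbol, a mean log2 CPM of at least 1, an adjusted p under 0.05 and no overlap between the 4 and 4 values. Of these it names the 8 largest increases and 8 largest decreases at 5 µM against control, and the 5 and 5 of each other comparison. It adds 21 genes whatever their values, for the HIF, EMT, p53 and topoisomerase questions and hepatocyte identity, with MYC among them. From each list called at 5 µM it adds the 3 members with the smallest p, and from each other list with a changed member the 1 with the smallest. The rule gave 99 genes, of which some are not reported here. Other genes are named only where stated.

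The steps were tested on simulated data drawn from the library sizes and means of the real libraries, with 16839 genes. For 5 µM against control, 50%, 70%, 86% and 96% of genes changed by 1.25, 1.5, 2 and 4-fold were recovered, and 8.56% of calls were false. The recovered shares were 58%, 74%, 88% and 96% for 2.5 µM against control, with 4.79% false calls. They were 48%, 74%, 96% and 100% for the 2 doses against each other, with 6.22% false calls. A simulated list was called each time, and 0 of the other 33 lists were. In each run 50 genes were changed at each fold, far fewer than changed in the real data, and genes were drawn independently. The simulations therefore do not test scaling with most genes changed, or lists whose members vary together.

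The alternatives fixed in advance were RLE, upper quartile and library size scaling, DESeq2 1.42.0, limma-voom, other low count filters, the replicate number as a block, fits of only the groups compared, each library left out in turn, removal of the mitochondrial genes, a test against a minimum fold (glmTreat), camera with an estimated correlation, and fry. A correction for GC content and a run without processed pseudogenes and antisense genes were added after the data were seen. No library was left out of the reported results.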

Results

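The response of a human cell line to acriflavine was profiled by mRNA sequencing. Acriflavine is a mixture of acridine dyes that intercalates into DNA and is known to block the pairing of the subunits of hypoxia-inducible factor 1 (HIF-1). The study's title asks about the epithelial-to-mesenchymal transition (EMT), in which epithelial cells lose junctions and gain mesenchymal traits. The cells were labelled HepG2, a line from a human hepatoblastoma, and the sample descriptions name a derivative of it selected for resistance to the kinase inhibitor sorafenib. Control cultures are called untreated in one label, while the treatment protocol describes the vehicle DMSO. Each of the 3 groups (control, 2.5 µM and 5 µM for 24 h) had 4 libraries, and the labels call them biological replicates. Library totals were 11891849 to 14024568 counts in the controls, 13095641 to 15115510 at 2.5 µM and 10733567 to 15116842 at 5 µM.

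The 12 libraries fell into their 3 groups, with the 2.5 µM libraries between the others on the first principal component. This component held 75.9% of the variance of log2 CPM and the next 11.9%. Pearson correlations across genes were 0.992 to 0.994 within groups. They were 0.967 to 0.972 between control and 2.5 µM, 0.948 to 0.961 between the doses, and 0.901 to 0.915 between control and 5 µM. None of the 66 pairs of libraries held identical counts, and replicate pairs differed by more than sampling noise (chi-square per degree of freedom 1.72 to 5.75).

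**Figure D1:**
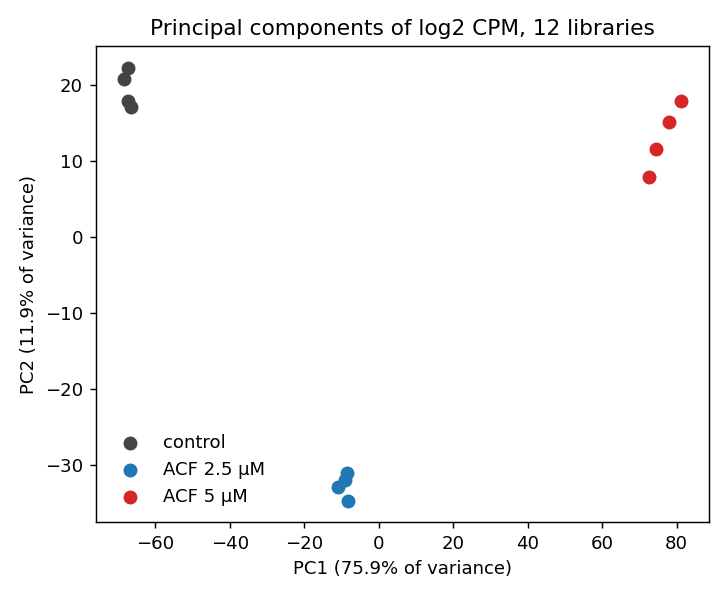
Principal components of log2 CPM over the tested genes, with 1 point per library (4 control, 4 at 2.5 µM, 4 at 5 µM); the horizontal axis is component 1 (75.9% of the variance) and the vertical axis component 2 (11.9%), both in component scores. The 4 libraries of each group lie together and apart from the other groups.

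Genes of the hepatocyte secretory programme were close to absent in these libraries, controls included. Albumin (ALB) and alpha-fetoprotein (AFP), 2 abundant products of fetal liver cells, had 2 counts each over the 12 libraries. Both had 0 in the controls, which allows up to 0.0582 CPM there (without TMM scaling). Of the 30 matched secreted proteins, 29 were under 1 CPM in the controls. Complement C3 was the exception, at 677 ± 34.6 CPM (SD, n = 4). CPS1, the first enzyme of the urea cycle, was abundant at 2180 ± 45 CPM in the controls and fell to 945 ± 15 CPM at 5 µM. Only 6 secreted protein genes and 10 hepatocyte transcription factor and metabolism genes had enough counts to be tested.

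At 5 µM, replication-dependent histone genes, p53 targets, xenobiotic response genes and lysosomal genes rose as groups. Mitochondrially encoded mRNAs, ATF4 target genes, cytosolic ribosomal proteins, ribosome biogenesis, DNA replication, DNA repair, endoplasmic reticulum chaperone and cholesterol synthesis genes fell as groups. These are the 12 of 33 lists called by camera, and their adjusted p lay between 0.0668 and 0.429 with an estimated correlation. Expression changed for 13165 of 16839 genes (78.2%) in edgeR's quasi-likelihood test at an adjusted p of 0.05, with 6524 higher and 6641 lower. Which side held more genes depended on the scaling, with 6741 higher and 6372 lower by RLE, 6931 and 6223 by upper quartile, and 7641 and 5464 by library size. Of these, 4445 changed at least 2-fold, 2632 up and 1813 down. The 4 and 4 values did not overlap for 70.8% of genes, where chance gives 2.86%.

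The largest increases at 5 µM were in genes close to silent in the controls. LGR5 (ENSG00000139292), a receptor of R-spondins and a stem cell marker, had 0 control counts and reached 6.55 ± 1.45 CPM (SD, n = 4), at least 109-fold higher. ZNF423, a zinc finger transcription factor, and TF, which encodes transferrin, also had 0 control counts and were at least 99.2-fold and 89.1-fold higher. IGF2 (ENSG00000167244), a fetal growth factor, went from 0.115 ± 0.0946 to 38.6 ± 9.63 CPM, a log2 fold change of 8.21 ± 0.33 (adjusted p = 2.47e-13). From 1 to 3 control counts, PLEK rose by a count ratio of 350 (95% interval 62.5 to 13900) and CGA, the shared subunit of glycoprotein hormones, by 235 (80.1 to 1140). The antisense genes CALML3-AS1 and YWHAH-AS1 had 1 control count each and count ratios of 508 (90.8 to 20100) and 459 (82.1 to 18200). The counting is not stated to use strand, so reads of these 2 cannot be told from those of genes on the other strand. Libraries at 5 µM also had more genes with 5 or more counts, 18498 ± 400 against 16894 ± 203 in the controls (SD, n = 4).

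The largest decreases included KRT16 (ENSG00000186832), a keratin of stressed epithelia, which fell from 21.0 ± 3.91 to 0.557 ± 0.201 CPM (log2 fold change -5.18 ± 0.20, adjusted p = 1.46e-21). XPOT, which exports tRNA from the nucleus, fell from 354 ± 11.5 to 14.3 ± 1.62 CPM (-4.64 ± 0.06), with its pseudogene XPOTP1 (-4.44 ± 0.09), and how reads were divided between these copies is uncertain. The others of this set were the homeobox gene LHX6 (-4.32), the activin subunit INHBE (-4.06), the pseudogene CHORDC1P4 (-3.93), the matrix gene ECM2 (-3.85) and alanine transaminase GPT (-3.68). CHORDC1P4 shares sequence with the heat shock gene CHORDC1, which itself fell from 33.7 ± 4.54 to 3.46 ± 0.280 CPM.

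HIF-1 subunit mRNAs fell at 5 µM, while HIF target genes as a list did not move one way. HIF1A (ENSG00000100644) fell from 357 ± 46.1 to 109 ± 12.5 CPM (log2 fold change -1.72 ± 0.11, adjusted p = 8.04e-09), and its partner ARNT from 101 ± 2.07 to 30.0 ± 2.29 CPM (-1.75 ± 0.06). EPAS1, which encodes HIF-2 alpha, fell by less (-0.37 ± 0.05). The target VEGFA, an angiogenic factor, fell from 132 ± 10.8 to 77.2 ± 5.79 CPM, whereas NDRG1 rose from 125 ± 7.29 to 576 ± 21.2 CPM. CA9 had a mean of at most 0.159 CPM in any group and was not tested. Of 28 HIF targets outside glycolysis, 12 rose, 10 fell and 6 did not pass (camera adjusted p = 0.86). Of 21 glycolysis genes, 4 rose and 14 fell, among them the lactate exporter SLC16A3 (-2.41 ± 0.05), and the list missed the threshold (adjusted p = 0.0538). That list passed in 11 of its 21 alternatives, over which the adjusted p ran from 0.00268 to 0.13. Among these were the runs without control replicate 1 (0.0338), 2 (0.0338) or 4 (0.0442), without 2.5 µM replicate 1 (0.0484), 2 (0.0489), 3 (0.0481) or 4 (0.044), and without 5 µM replicate 1 (0.0397).

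EMT genes moved in both directions at 5 µM. CDH1 (ENSG00000039068), which encodes E-cadherin, was close to silent in the controls, with 18 counts over the 4 libraries. It rose from 0.359 ± 0.135 to 4.86 ± 0.568 CPM (SD, n = 4, log2 fold change 3.70 ± 0.27, edgeR adjusted p = 2.62e-14). The intermediate filament gene VIM fell from 1890 ± 119 to 1280 ± 26.4 CPM (-0.56 ± 0.04), and fibronectin FN1 (-0.34 ± 0.05) and the EMT regulator ZEB1 (-0.42 ± 0.10) fell too. SNAI1, a repressor of CDH1, rose from 5.52 ± 1.06 to 12.4 ± 1.81 CPM (1.17 ± 0.13). CDH2, which encodes N-cadherin, was at 257 ± 7.30 and 248 ± 3.95 CPM (adjusted p = 0.221), and SNAI2 at 19.3 ± 2.02 and 17.7 ± 2.26 CPM (adjusted p = 0.178; 0.0442 without control replicate 4, and 0.0442 to 0.99 over 24 alternatives). TWIST1 did not pass (0.16 ± 0.08, adjusted p = 0.0762), but did with 3 other scalings, such as library size (0.30, adjusted p = 0.00215, range over 24 alternatives 0.00215 to 0.616). Of 27 epithelial genes, 14 rose and 9 fell, with the protease inhibitor SPINT1 up 7.96-fold (camera adjusted p = 0.184). Of 25 mesenchymal genes and EMT regulators, 11 rose and 10 fell, with smooth muscle actin ACTA2 up 16.5-fold (adjusted p = 0.749). The median of that list was -0.06 and its mean 0.60. Of 24 TGF-beta targets, 14 rose and 8 fell, with ID2 up 13.2-fold (adjusted p = 0.213), and TGFB1 itself rose slightly (0.20 ± 0.06), which did not pass with the GC correction (0.09, adjusted p = 0.0534, the highest over 24 alternatives).

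**Figure D2:**
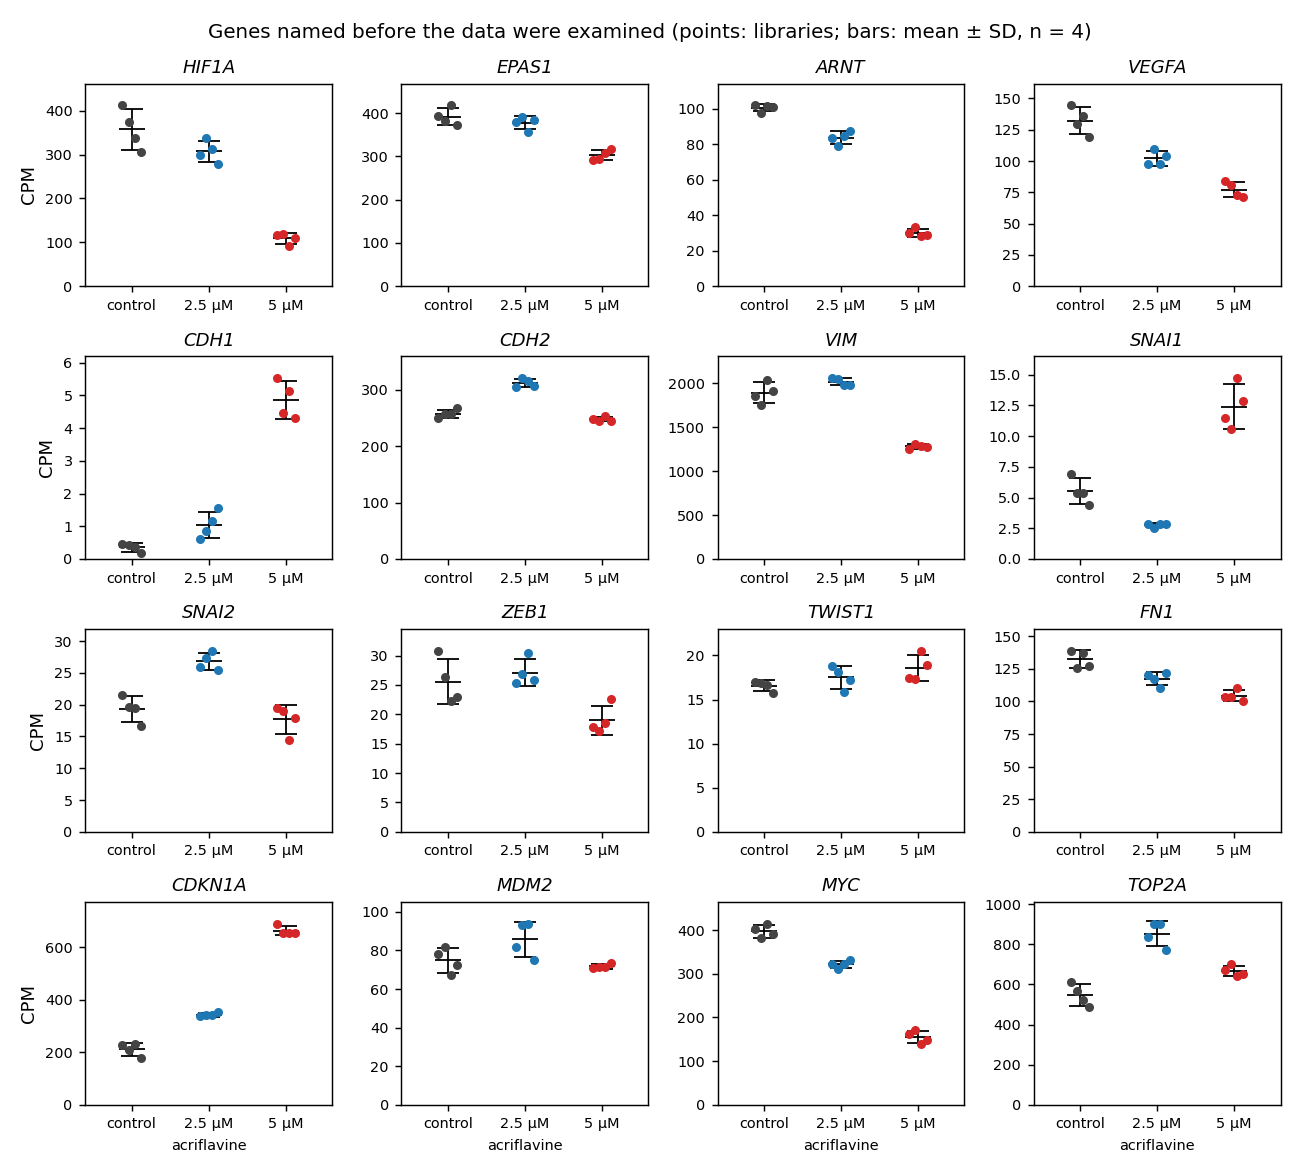
CPM of 16 genes fixed before the data were examined, 1 panel per gene, against acriflavine dose (control, 2.5 µM, 5 µM); points are libraries and bars the mean ± SD (n = 4), and each CPM axis starts at 0. HIF1A, ARNT and MYC were lowest at 5 µM (109, 30.0 and 155 CPM), CDKN1A and CDH1 highest (664 and 4.86 CPM), and SNAI1 was lowest at 2.5 µM (2.79 CPM).

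Genes of the p53 response and histone genes rose at 5 µM. CDKN1A (ENSG00000124762), which encodes the cell cycle inhibitor p21, rose from 211 ± 24.4 to 664 ± 17.8 CPM (log2 fold change 1.65 ± 0.06, adjusted p = 4.83e-22), with DDB2 (1.46) and BTG2 (1.62). Of 29 p53 targets, 22 rose and 2 fell, with a median of 0.71 (camera adjusted p = 0.000215; adjusted p = 0.0668 with an estimated correlation). MDM2, the p53 antagonist, was not past the test (-0.07 ± 0.07, adjusted p = 0.36). All 12 tested histone genes rose, with a median of 2.75 (adjusted p = 1.35e-05; adjusted p = 0.255 with an estimated correlation). H4C8 went from 1.11 ± 0.535 to 53.8 ± 5.38 CPM, H2AC11 rose 20.1-fold and H2AC6 8.62-fold, all members of families of similar copies. Replication-dependent histone mRNAs mostly lack poly-A tails, so counts from poly-A libraries need not follow their full level in the cells. Of 24 autophagy and lysosome genes, 14 rose and 2 fell, with the sialidase NEU1 up 6.59-fold, ATP6V0D1 2.69-fold and GABARAPL1 2.42-fold (adjusted p = 0.0113; adjusted p = 0.359 with an estimated correlation). That call was lost with the GC correction (adjusted p = 0.0899, range over 21 alternatives 0.00412 to 0.0899), with a median of 0.38 (quartiles -0.07 and 0.77) against 0.36 (-0.03 and 0.81) before and a mean of 0.39 against 0.45. Of 6 xenobiotic response genes tested, out of 20 listed, 5 rose and 0 fell, with NQO1 (0.97), TIPARP (1.28) and AHRR (1.03). NQO1 is also on the list of NRF2 targets, of which 3 rose and 11 fell. The adjusted p of the xenobiotic response list was 0.0316, with adjusted p = 0.345 with an estimated correlation, and the call was lost without a low count filter (adjusted p = 0.122, the highest over 21 alternatives).

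ATF4 and CHOP targets, ribosomal protein, ribosome biogenesis and endoplasmic reticulum chaperone genes fell as lists at 5 µM, the last with the reported scaling only. ATF4, the transcription factor of the amino acid response, fell from 408 ± 10.4 to 79.3 ± 5.52 CPM (log2 fold change -2.37 ± 0.05, adjusted p = 2.20e-28). The tRNA synthetases AARS1 (-2.51) and GARS1 (-2.25) fell with it, whereas ATF3 on the same list rose from 26.4 ± 2.24 to 160 ± 13.8 CPM. Of 24 ATF4 and CHOP targets, 3 rose and 19 fell, with a median of -1.31 (adjusted p = 3.82e-05; adjusted p = 0.359 with an estimated correlation). Of 34 cytosolic ribosomal protein genes, 1 rose and 30 fell, with RPL5 (-1.05), RPL27 (-0.95) and RPL4 (-0.85) (adjusted p = 1.07e-05; adjusted p = 0.371 with an estimated correlation). Of 29 ribosome biogenesis genes, 4 rose and 18 fell, with GNL3 (-1.70), NPM1 (-1.30) and MYC, which fell from 398 ± 14.5 to 155 ± 14.3 CPM (adjusted p = 0.00366; adjusted p = 0.429 with an estimated correlation). The endoplasmic reticulum chaperone list also holds genes that are not chaperones, such as the transcription factor XBP1. Of its 22 genes, 4 rose and 13 fell, with XBP1 (-1.42), HSPA5 (-1.44) and CANX (-0.71) (camera adjusted p = 0.0425, and 0.359 with an estimated correlation). This last call was lost in 6 of 21 alternatives, over which the adjusted p ran from 0.00165 to 0.0956. Among them were all 3 other scalings (RLE 0.0513, upper quartile 0.0587, library size 0.0956) and the run without 5 µM replicate 2 (0.063).

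DNA replication, DNA repair and cholesterol synthesis genes also fell. Of 34 replication genes, 5 rose and 22 fell, with RRM2, a subunit of ribonucleotide reductase, down from 345 ± 5.49 to 126 ± 5.14 CPM, and with MCM4 (-0.83) and CDC45 (-0.95) (camera adjusted p = 0.0106; adjusted p = 0.359 with an estimated correlation). Of 35 repair genes, 5 rose and 23 fell, with the ligase LIG1 (-1.60), FANCI (-1.16) and PARP1 (-0.79) (adjusted p = 0.00996; adjusted p = 0.312 with an estimated correlation). Of 24 cholesterol synthesis genes, 3 rose and 17 fell, with DHCR7 (-1.98) and SQLE (-2.13) (adjusted p = 0.00595; adjusted p = 0.281 with an estimated correlation). Of 32 mitosis genes, 12 rose and 12 fell (adjusted p = 0.986), with PRC1 up 2.13-fold. Of 10 topoisomerase genes, 4 rose and 3 fell, among them TOP1 (0.34), TOP2A (0.28) and TOP3B (1.57) (adjusted p = 0.86).

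RNAs of the mitochondrial genome moved apart by class. All 13 mRNAs fell at 5 µM, with a median of -1.25 (camera adjusted p = 1.07e-05; adjusted p = 0.359 with an estimated correlation). MT-CO2, a subunit of cytochrome c oxidase, fell from 3590 ± 99.0 to 1320 ± 43.7 CPM (log2 fold change -1.45 ± 0.05, adjusted p = 5.69e-22), MT-ND4L by -1.46, and MT-ND6 from 29.6 ± 2.92 to 4.04 ± 0.714 CPM. The 2 ribosomal RNAs of the same genome, looked at after the data were seen, rose. MT-RNR2 went from 10400 ± 1520 to 17300 ± 1650 CPM (0.73 ± 0.12) and MT-RNR1 from 722 ± 70.9 to 4050 ± 552 CPM (2.49 ± 0.15, adjusted p = 8.00e-08). Nuclear genes of oxidative phosphorylation went both ways (14 rose and 14 fell of 35, NDUFB10 -1.19, adjusted p = 0.644).

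**Figure D3:**
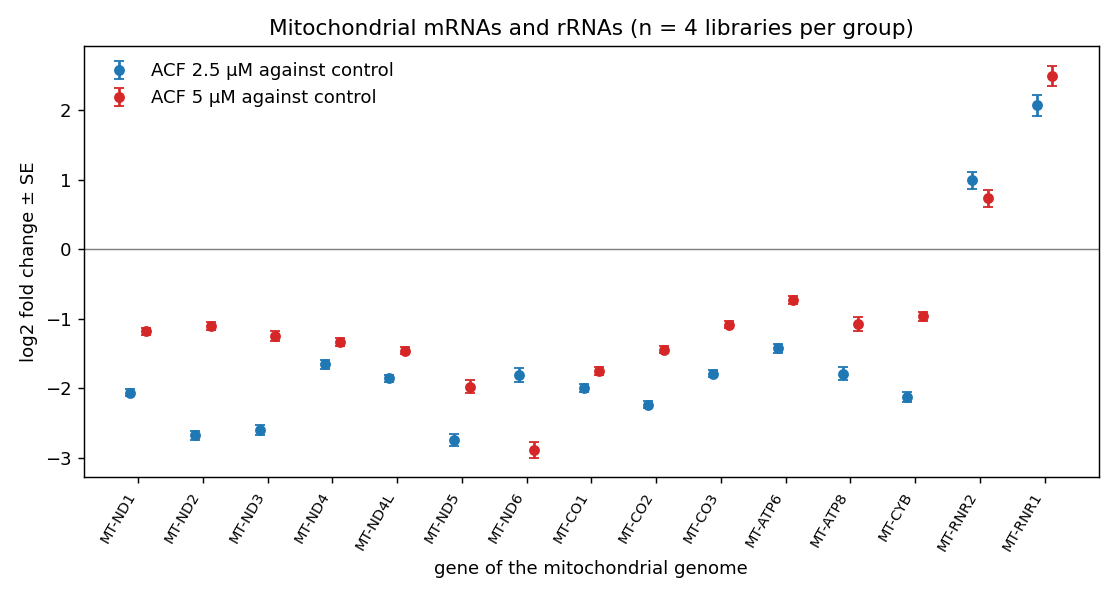
Log2 fold change ± SE against control (vertical axis) of the 13 mRNAs and 2 ribosomal RNAs of the mitochondrial genome (horizontal axis) at 2.5 µM and 5 µM, n = 4 libraries per group. All mRNAs lie below 0, from -2.89 to -0.73 at 5 µM, and both ribosomal RNAs above it.

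The other lists were not called at 5 µM (camera adjusted p in brackets). Of 22 NRF2 targets, 3 rose and 11 fell (0.161), and of 20 cytosolic heat shock genes 4 rose and 13 fell (0.105). Of 18 fatty acid synthesis genes, 6 rose and 11 fell, with FASN down 3.27-fold (0.184). Of 18 interferon-stimulated genes, 10 rose and 6 fell, with IFIT3 up 3.75-fold (0.169), and of 18 NF-kB genes 7 rose and 9 fell, with NFKB1 down 4.43-fold (0.523). Of 21 immediate early genes, 9 rose and 10 fell (0.754), of 11 WNT targets 3 rose and 4 fell (0.926), and of 28 apoptosis regulators 15 rose and 7 fell, with BMF up 14.9-fold (0.319). Of 7 metallothionein and zinc genes, 1 rose and 5 fell, with SLC39A14 at -0.53 (0.184). Of 6 hepatocyte secreted protein genes, 5 rose and 1 fell (0.0757), and of 10 hepatocyte transcription factor and metabolism genes 7 rose and 3 fell (0.479). All listed secreted protein genes but C3 were under 1 CPM in the controls, so a fall of the others could hardly be seen. Among markers of other cells, 3 of 7 fibroblast genes rose and 3 fell (0.644), and 3 of 9 cholangiocyte genes rose and 3 fell, with KRT19 down 3.97-fold (0.822). The 4 tested endothelial and 3 tested blood cell markers were too few for the list test. Of the endothelial genes 2 rose and 2 fell, with TEK up from 0.168 ± 0.132 to 6.24 ± 0.942 CPM. All 3 blood cell genes tested, of 14 listed, rose, with PTPRC at 2.27 ± 0.174 CPM from 2 control counts (count ratio 56.0, 95% interval 15.2 to 468). So few control counts leave room only for a rise.

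Adjusted over the list alone, the counts of members that rose and fell at 5 µM were the same for all 35 lists. Median, mean and test differed in sign for mesenchymal genes, topoisomerases, oxidative phosphorylation, WNT targets and cholangiocyte markers, and 0 of these 5 lists passed. With an estimated correlation camera called 0 lists, with 4 at an unadjusted p under 0.05, while fry, which asks only whether a list moves one way, called 30. At least 12 lists were called in 3 of the 35 ways to split the 8 libraries into 4 and 4, the real one included. With library size scaling the median of all genes moved from -0.02 to 0.12 on the log2 scale, and changes here are relative to the TMM scale.

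**Figure D4:**
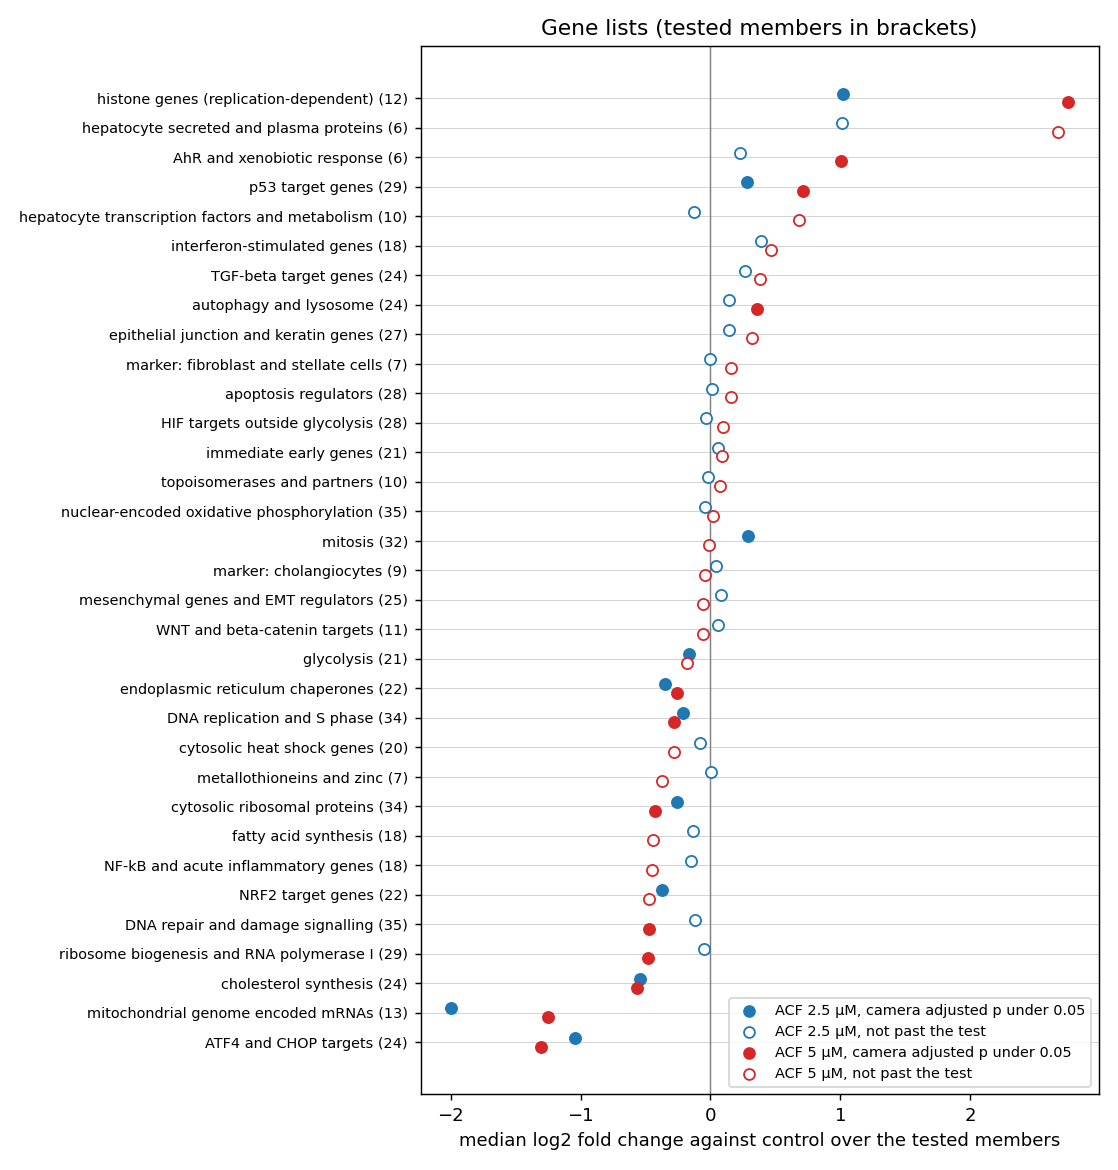
Median log2 fold change against control (horizontal axis) of the tested members of 33 gene lists (vertical axis, number of members in brackets) at 2.5 µM and 5 µM; filled points passed camera at an adjusted p of 0.05 and open points did not. Medians at 5 µM ran from -1.31 for ATF4 and CHOP targets to 2.75 for histone genes.

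At 2.5 µM, mitochondrially encoded mRNAs and ATF4 targets had the lowest medians of the gene lists. Cholesterol synthesis, ribosomal protein, replication, chaperone, glycolysis and NRF2 target genes also fell as groups, and histone, p53 target and mitosis genes rose. These are the 11 of 33 lists called, 3 up and 8 down, and their adjusted p lay between 0.0745 and 0.502 with an estimated correlation. Expression changed for 9957 of 16839 genes (59.1%), 5165 higher and 4792 lower (5042 and 5204 with the GC correction), and 1700 changed at least 2-fold (1070 up, 630 down). With only these 2 groups in the fit, and 15766 genes tested, 1294 did (701 up, 593 down). The 4 and 4 values did not overlap for 50.5% of genes, where chance gives 2.86%.

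The largest fitted increase at 2.5 µM was in the antisense gene FOSL2-AS1, from 0.504 ± 0.0723 to 33.8 ± 0.936 CPM (SD, n = 4; log2 fold change 6.04 ± 0.14, adjusted p = 4.67e-27). The next genes had at most 1 control count and cannot be ranked against it. LGR5 was at least 9.54-fold higher, and LOXL4, a lysyl oxidase of the matrix, had a count ratio of 43.8 (95% interval 7.5 to 1770) from 1 control count. CALML3-AS1 and YWHAH-AS1 had ratios of 65.3 (11.4 to 2610) and 56.3 (9.75 to 2260), also from 1 control count. KRT16 fell 45.5-fold, XPOTP1 10.9-fold, XPOT 9.81-fold, INHBE 9.72-fold and LHX6 9.63-fold.

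Mitochondrial mRNAs were lower at 2.5 µM than at 5 µM for 12 of the 13. All 13 fell against control, with a median of -2.0 (adjusted p = 1.83e-12; adjusted p = 0.164 with an estimated correlation), and MT-CO2 was at 757 ± 75.8 CPM. MT-RNR2 rose to 20800 ± 2560 CPM and MT-RNR1 to 3030 ± 548 CPM. Of 24 ATF4 and CHOP targets, 2 rose and 19 fell, with a median of -1.05 (adjusted p = 1.53e-09; adjusted p = 0.202 with an estimated correlation). Of 22 genes on the endoplasmic reticulum chaperone list, 1 rose and 16 fell, with HSPA5 from 1170 ± 57.4 to 416 ± 10.7 CPM (camera adjusted p = 4.69e-05, and 0.138 with an estimated correlation). Of 24 cholesterol synthesis genes, 3 rose and 20 fell (adjusted p = 3.03e-06; adjusted p = 0.0745 with an estimated correlation). Of 34 ribosomal protein genes, 1 rose and 29 fell (adjusted p = 1.37e-06; adjusted p = 0.394 with an estimated correlation), and of 34 replication genes 2 rose and 20 fell (adjusted p = 0.000664; adjusted p = 0.206 with an estimated correlation). Of 21 glycolysis genes, 3 rose and 12 fell (adjusted p = 0.0109; adjusted p = 0.502 with an estimated correlation). Of 22 NRF2 targets, 6 rose and 12 fell (adjusted p = 0.0454; adjusted p = 0.169 with an estimated correlation). The NRF2 call was lost in 6 of 21 alternatives (range 0.00732 to 0.0821), 4 of which left out a single 5 µM library (0.0514, 0.0578, 0.0538 and 0.0571 without replicates 1 to 4).

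Of 32 mitosis genes, 21 rose and 3 fell at 2.5 µM, with TOP2A from 547 ± 54.3 to 853 ± 61.8 CPM (SD, n = 4) and PRC1 up 1.73-fold (camera adjusted p = 0.000239; adjusted p = 0.202 with an estimated correlation). Of 29 p53 targets, 19 rose and 5 fell, with CDKN1A at 343 ± 7.01 CPM (adjusted p = 0.00946; adjusted p = 0.138 with an estimated correlation). MDM2 rose by 0.19 ± 0.06 (adjusted p = 0.0114), which was lost without control replicate 3 (0.12, adjusted p = 0.11), 2.5 µM replicate 2 (0.0612) or 2.5 µM replicate 3 (0.0593), over a range of 0.00138 to 0.11 in 24 alternatives. Of 12 histone genes, 9 rose and 1 fell (adjusted p = 0.0054; adjusted p = 0.293 with an estimated correlation).

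HIF1A did not pass at 2.5 µM, and SNAI1 and TGFB1 moved the other way than at 5 µM. HIF1A was at 307 ± 24.4 CPM (log2 fold change -0.22 ± 0.10, adjusted p = 0.0779), and passed in 7 of 24 alternatives (range 0.00552 to 0.191), such as without control replicate 4 (-0.29, adjusted p = 0.014), 2.5 µM replicate 2 (0.0456) or 5 µM replicate 3 (0.0151). ARNT (-0.26 ± 0.05) and VEGFA (-0.37 ± 0.06) fell, and EPAS1 did not pass (-0.05, adjusted p = 0.338). Of 28 HIF targets, 8 rose and 12 fell (camera adjusted p = 0.43). CDH1 rose to 1.04 ± 0.407 CPM (1.5 ± 0.37), CDH2 to 311 ± 7.43 CPM (0.27 ± 0.04) and SNAI2 to 26.8 ± 1.36 CPM (0.47 ± 0.09). SNAI1 fell to 2.79 ± 0.171 CPM (-0.99 ± 0.16) and TGFB1 fell by 0.46 ± 0.06 on the log2 scale. VIM (0.09, adjusted p = 0.0675) passed in 4 of 24 alternatives (0.00226 to 0.277), such as without control replicate 3 (0.0228). Epithelial genes (12 rose and 7 fell of 27, adjusted p = 0.208) and mesenchymal genes and EMT regulators (7 rose and 8 fell of 25, adjusted p = 0.625) were not called.

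Adjusted over the list alone, the counts at 2.5 µM differed by 1 gene in 6 of the 35 lists, among them mitosis (22 rose) and ribosomal proteins (2 rose). Median, mean and test differed in sign for 5 lists that were not called, namely hepatocyte transcription factors, topoisomerases, NF-kB genes, metallothioneins and fibroblast markers. With an estimated correlation camera called 0 lists, with 8 at an unadjusted p under 0.05, and fry called 31. At least 11 lists were called in 4 of the 35 splits of the 8 libraries, the real one included.

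Between the doses, IGF2 and 4 other genes of low level at 2.5 µM rose most, and 12 of 13 mitochondrial mRNAs were higher at 5 µM than at 2.5 µM. IGF2 was at 0.128 ± 0.0412 CPM at 2.5 µM and 38.6 ± 9.63 CPM at 5 µM (SD, n = 4; log2 fold change 8.15 ± 0.32, adjusted p = 4.35e-13). DISP3 (6.38 ± 0.40), ATP1B2, a subunit of the sodium pump (5.22 ± 0.15), CCM2L (5.20 ± 0.39) and TF (5.14 ± 0.31) followed. The largest decreases were in BEST2 (-2.28), AATK (-2.18), CHORDC1P4 (-2.17), PUS7 (-2.15) and the nuclear RNA NEAT1, from 140 ± 8.17 to 32.2 ± 8.07 CPM (-2.14 ± 0.17). Expression differed for 11526 genes (68.4%), 5660 higher and 5866 lower at 5 µM, and 2209 differed at least 2-fold (1703 up, 506 down). More genes were higher than lower with RLE (6077 and 5388), upper quartile (6240 and 5184) and library size scaling (6649 and 4734). The groups did not overlap for 62.1% of genes, where chance gives 2.86%.

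Of the lists, 8 of 33 were called between the doses. Histone genes (12 of 12 rose, adjusted p = 5.35e-06; adjusted p = 0.174 with an estimated correlation) and p53 targets (22 rose and 4 fell of 29, adjusted p = 0.00123; adjusted p = 0.117 with an estimated correlation) were higher at 5 µM. Mitochondrial mRNAs were also higher (12 of 13, MT-ND6 lower, adjusted p = 0.000476; adjusted p = 0.525 with an estimated correlation), as were autophagy and lysosome genes (15 rose and 4 fell of 24, adjusted p = 0.00858; adjusted p = 0.464 with an estimated correlation). Ribosome biogenesis (4 rose and 22 fell of 29, adjusted p = 0.000331; adjusted p = 0.516 with an estimated correlation) and ribosomal proteins (3 rose and 22 fell of 34, adjusted p = 0.0141; adjusted p = 0.887 with an estimated correlation) were lower. So were mitosis genes (7 rose and 22 fell of 32, adjusted p = 0.00921; adjusted p = 0.511 with an estimated correlation) and DNA repair genes (7 rose and 22 fell of 35, adjusted p = 0.02; adjusted p = 0.464 with an estimated correlation). SNAI1 was higher at 5 µM (2.16 ± 0.14), and HIF1A (-1.50 ± 0.11), CDH2 (-0.33 ± 0.04) and VIM (-0.66 ± 0.04) were lower. With the GC correction the autophagy (adjusted p = 0.0658, range over 21 alternatives 0.00465 to 0.0658), mitosis (0.0952, range 4.96e-05 to 0.0952) and DNA repair calls (0.0815, range 0.000139 to 0.0815) were lost. Their medians went from 0.33 (quartiles 0.03 and 0.56) to 0.24 (0.06 and 0.54), from -0.33 (-0.61 and -0.03) to -0.25 (-0.49 and 0.07) and from -0.25 (-0.60 and -0.04) to -0.23 (-0.51 and 0.10). The same correction gained the glycolysis list, with a median of -0.25 against -0.12 (adjusted p = 0.0279 against 0.544, range 0.0279 to 0.662). Adjusted over the list alone, counts differed by 1 in 4 lists (glycolysis, endoplasmic reticulum chaperones, oxidative phosphorylation and fatty acid synthesis). Median, mean and test differed in sign for 5 lists, none called (NRF2, oxidative phosphorylation, immediate early, WNT and cholangiocyte genes). With an estimated correlation camera called 0 lists, with 2 at an unadjusted p under 0.05, and fry called 27.

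Most genes changed at 5 µM had an intermediate mean at 2.5 µM. Of the 13165, 9493 (72.1%) had a 2.5 µM mean between those of the control and 5 µM, 11020 (83.7%) had the same sign at both doses, and the median ratio of the log2 fold changes was 0.428. Simulated 20 times with no effect at 2.5 µM and the observed one at 5 µM, these shares were 52.0% (51.5 to 52.7) and 52.1% (51.5 to 52.8). Over all tested genes 78.1% had the same sign, against 67.0% simulated with no effect at either dose and 76.4% with the controls split between the doses. By call, 2498 genes rose at 2.5 µM and again from 2.5 to 5 µM, and 2356 fell in both steps. A further 1326 rose and then fell, and 1001 fell and then rose. Against control, 435 genes were up at 2.5 µM and down at 5 µM, and 276, such as SNAI1 and TGFB1, were down and then up. Log2 fold changes of the doses correlated across genes with r = 0.807. Groups with no effect, simulated 20 times against the same 4 controls, gave 0.525, and with the controls split between the doses r was 0.749 (0.740 to 0.760 over the 6 splits). The covariance was 0.755, against 0.0299 simulated with no effect, a difference of 0.725. Both doses raised 3974 genes and lowered 3922, where independent lists would share 2001 and 1890, a value that leaves out the shared controls. With the controls split between the doses, 3250 and 3365 were shared (medians of 6 splits), and 0 and 0 in edgeR with no effect simulated. Genes are not independent replicates, and no p is attached to these values.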

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

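The tests of depth, of genomic DNA and of GC content in this part were chosen after the result was seen. The splits of the libraries were planned before.

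Genes left out of the tests for low counts held more of the library at 5 µM, a signal outside the comparisons of the report and above the controls. Their summed level was 1940 ± 67.1 CPM there (SD, n = 4) over 14142 genes with at least 1 count, against 1050 ± 30.6 in the controls (1030 to 1090) and 1070 ± 32.8 at 2.5 µM. Among tested genes, 188 rose at 5 µM from at most 3 control counts, 104 of them protein-coding, and 4 fell to at most 3 counts.

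Several technical explanations were weighed for this gain in detected genes. Depth is argued against, since after thinning each library to 10733567 counts every 5 µM library still had at least 1523 more genes with 5 or more counts than any control (means 16529 ± 62 in controls and 18170 ± 41 at 5 µM). Genomic DNA, which would raise silent genes alike per kb, is argued against by a gain 23.5 to 55.9 times larger in 5845 other silent protein-coding genes than in 345 olfactory receptor genes (5.32 to 13.3 times without the top 10% of genes). GC content is argued against as the whole cause, since with each library thinned to equal totals inside 20 bins of GC content the smallest such difference was 1457 genes (means 16193 ± 54 and 17737 ± 42; bin shares at 5 µM were 0.88 to 1.1 times those of the controls before thinning). Among tested markers of other cells at 5 µM, all 3 blood cell genes rose, and 2 of 4 endothelial genes rose and 2 fell. Of 7 fibroblast and 9 cholangiocyte genes, 3 rose and 3 fell each. RNA of other cells was not tested further for this pattern and stays open, as does an effect of the solvent, so expression of many silent genes under the drug may be no more than a hypothesis here.

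Of 315 groups of 4 values, 23 had 1 library far from the other 3, by a gap past Dixon's 95% limit, where chance gives about 1 in 20, or 16. In 8 of them, 1 library of the group had counts and the others had 0. CALML3-AS1 (0.0846 CPM, control replicate 4), YWHAH-AS1 (0.0895, control replicate 3), PLEK and LOXL4 (0.0781 each, control replicate 1) and PTPRC (0.156, control replicate 1) had counts in 1 control only. ALB (0.147, 5 µM replicate 3) and AFP (0.0672, 2.5 µM replicate 4, and 0.0733, 5 µM replicate 3) likewise had counts in 1 library of their group.

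In the other 15, all 4 libraries had counts, though few for IGF2 and PTPRC at 2.5 µM (7 and 19 over the 4 libraries) and KRT16 at 5 µM (30). At 5 µM, replicate 1 had 5.1% of its counts in the 10 most abundant genes (others 4.58 to 4.62%) and 690 CPM of CDKN1A (654 to 656). Replicate 2 had 0.258 CPM of KRT16 (0.624 to 0.687), replicate 3 had 8.72 CPM of LGR5 (5.61 to 5.94), and replicate 4 had 146 CPM of TOP1 (135 to 136) and 325 of GABARAPL1 (291 to 295). At 2.5 µM, replicate 1 had 204 CPM of RRM2 (209 to 210), replicate 2 had 2.53 of SNAI1 (2.85 to 2.89) and replicate 3 had 0.539 of PTPRC (0.269 to 0.303). Replicate 4 had 0.0672 CPM of IGF2 (0.141 to 0.154) and 6.26% of counts in processed pseudogenes (6.20 to 6.21%). Among the controls, replicate 1 had 192 CPM of AATK (182 to 183), replicate 3 had 48.2 of SQLE (52.4 to 53.1), and replicate 4 had 55.2 of DDB2 (61.9 to 62.9) and 14.2 of BTG2 (17.0 to 17.5).

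Each comparison was repeated for all 35 splits of its 8 libraries into 4 and 4. Chance can be excluded at 0.05 for the counts of changed genes, with or without the 2-fold minimum. In edgeR the real split alone (1 of 35) gave 9957, 13165 and 11526 genes, and 1700, 4445 and 2209 at least 2-fold, and the highest of the other 34 was 0. This is the smallest share that 35 splits allow, not adjusted for the number of counts. The other splits mix conditions within their groups, which widens the spread, so their 0 is not the count to be had without an effect. At an unadjusted p under 0.05 the highest others were 2805, 2378 and 2971, against 10601, 13331 and 11902. For the number of called lists, chance cannot be excluded at 2.5 µM (11 called, highest other 12, 4 of 35 as large) or at 5 µM (12 called, highest other 13, 3 of 35). The other splits as large had exchanged 1 library of each group, which leaves part of the contrast in them, and the 18 that exchanged 2 called at most 3 lists in either comparison, a division made after the result was seen. Between the doses it can be, with the preset correlation and by 1 list (8 called, highest other 7, 1 of 35). There 6 lists were called with the GC correction, 7 without the mitochondrial genes and 0 with an estimated correlation (2 at an unadjusted p under 0.05, and 27 by fry), and splits were not run under these settings.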

How the results depend on the processing

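The GC correction and the run without processed pseudogenes and antisense genes were chosen after the data were seen, and the other alternatives before. No direction of a called list or named gene was reversed in any alternative. Total counts of changed genes stayed within 1.5 times the reported ones with RLE, upper quartile and library size scaling, DESeq2, limma-voom, fits of only the groups compared and the removal of mitochondrial genes or pseudogenes, but 701 and not 1070 genes were at least 2-fold up at 2.5 µM with only the groups compared, where fewer genes were tested. Against a minimum fold of 1.5 (glmTreat), 2005, 6205 and 3182 genes passed at 2.5 µM, at 5 µM and between the doses, since the test asks for a larger change, and 66 of 288 named gene results were lost. Without a low count filter, 7063 genes changed at least 2-fold at 5 µM (4800 up, 2263 down) and 4044 between the doses (3366 up, 678 down), since more genes were tested. Camera with an estimated correlation called 0, 0 and 0 lists and fry 31, 30 and 27. The first uses the correlation of members estimated in these libraries, and fry does not compare a list with other genes. The correlation of the doses was 0.749 with split controls, where the doses share no control, and 0.785 at a mean log2 CPM of at least 3, and the cause of the latter was not tested.

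With each library left out in turn, 9382 to 9955 genes changed at 2.5 µM (1736 to 1775 at least 2-fold), 12856 to 13457 at 5 µM (4462 to 4778) and 10928 to 11868 between the doses (2196 to 2473). Called lists numbered 10 to 12, 11 to 13 and 8 in each run, and 9458 to 9751 genes had an intermediate level at 2.5 µM. With the replicate number as a block, 9828, 13091 and 11423 genes changed, 11, 12 and 8 lists were called, and 9460 genes were intermediate. The block gave 2 further calls of named genes at 2.5 µM, HIF1A (-0.21, adjusted p = 0.00552, range over 24 alternatives 0.00552 to 0.191) and ATP1B2 (0.67, adjusted p = 0.0412, range 0.039 to 0.189), and changed no other call of a list or named gene. Same-numbered libraries correlated by -0.13 to 0.074 in their deviations, 0 of 12 pairs over 0.1, and 0 libraries correlated best with their own number in both other groups, so the numbers are not read as pairs.

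Over all alternatives except glmTreat, the estimated correlation and fry, the GC correction among them, 17 of 2076 list values lost a call and 20 gained one, and 16 of 6876 named gene values lost and 20 gained one. Further calls that turned on 1 library were as follows. TEK at 2.5 µM was lost without 2.5 µM replicate 1 (1.18, adjusted p = 0.0911, range over 23 alternatives 0.0024 to 0.0911), and ATP1B2 there gained a call in 3 alternatives, such as without 5 µM replicate 3 (0.67, adjusted p = 0.0409, range over 24 0.039 to 0.189). DNA repair at 2.5 µM gained one in 2 alternatives, such as without control replicate 3 (-0.19, adjusted p = 0.0419, range over 21 0.032 to 0.146). Between the doses LHX6 was lost in 8 alternatives, 4 of them without 2.5 µM replicate 1 or 3 or 5 µM replicate 1 or 2 (adjusted p 0.134, 0.0613, 0.087 and 0.125, range over 23 0.0253 to 0.134). Depth limits genes near 0: CA9, ALB and AFP had too few counts to test.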

Other observations

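The tests of drug effect, counting and cell identity, and of mitochondrial genome number and composition, and those of RNAs without poly-A tails for the mRNA fall and MT-RNR1, were chosen after the results were seen. That of such RNAs by the small RNA median, first set for both ribosomal RNAs and kept here for MT-RNR2, and that of gene span were written before.

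Noncoding classes rose with dose. Antisense-class genes held 0.252 to 0.265% of counts in the controls, 0.308 to 0.318% at 2.5 µM and 0.494 to 0.506% at 5 µM, and lincRNA genes 0.265 to 0.288%, 0.318 to 0.331% and 0.383 to 0.396%. Processed pseudogenes went the other way, from 6.52 to 6.80% in the controls to 5.84 to 5.96% at 5 µM. All 4 libraries at 5 µM lay apart from all 4 controls in these 3 shares. The exact 2-sided permutation p of 0.0286 each, the smallest that 4 against 4 allows, only restates this. It is not adjusted for the number of shares computed. Other shares overlapped, namely that of mitochondrial genes (3.24 to 3.67% in the controls, 3.11 to 3.69% at 5 µM) and that of the 10 most abundant genes (4.53 to 4.89%, 4.58 to 5.1%). The antisense share is of genes so classed, since the counting is not stated to use strand.

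Secreted hepatocyte proteins were near 0 although the cells were labelled HepG2, a line known to secrete albumin and alpha-fetoprotein, while the urea cycle gene CPS1 was abundant (2180 ± 45 CPM in the controls). Loss through the drug is argued against, since 29 of 30 secreted protein genes were already under 1 CPM in the controls, with C3 the exception. Another cell line under this label remains a possible explanation, with a highest ALB or AFP level of 0.147 CPM in any library, and it cannot be told apart from a sorafenib-selected derivative that lost these genes, because no other HepG2 library was analysed here. Loss of these genes in mapping or counting stays open too, since 6 of 30 had at least 100 counts over the 12 libraries, too few to exclude it for the others.

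Mitochondrial mRNAs fell while ribosomal RNAs of the same genome rose. Composition is argued against, since without the 2 ribosomal RNAs the median of the 13 mRNAs was -1.26 at 5 µM and -2.01 at 2.5 µM. More RNA without poly-A tails in the treated libraries is argued against for the mRNA fall at 2.5 µM. The smallest fall there was -1.43, where the median of all tested genes was 0.019. The same check was not made at 5 µM, where the smallest fall was -0.73 (MT-ATP6) and the median of all tested genes -0.015. Whether more RNA without such tails gave the rise of MT-RNR1 was not settled. MT-RNR1 lay at least 1.31 above the upper quartile of 9 small RNA genes (0.76 at 2.5 µM and 0.67 at 5 µM), although 1 of these, SNORA14B, picked out after its value was seen, rose by 2.14 at 5 µM. Replication-dependent histone mRNAs, which mostly lack such tails too, rose by a median of 1.02 at 2.5 µM and 2.75 at 5 µM, where MT-RNR1 rose by 2.07 and 2.49. For MT-RNR2 (0.99 and 0.73) more RNA without tails cannot be told apart from a change in the cells, since the small RNA genes had a median of 0.45 at 2.5 µM and -0.05 at 5 µM and went both ways. Fewer mitochondrial genomes alone would lower MT-RNR1 too, which rose by at least 2.07, but this speaks against them only if that rise took place in the cells. Fewer genomes as whole or part of the mRNA fall therefore stay open, as does an effect of the drug on mitochondrial transcripts, which was not tested directly.

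A DNA-binding drug could impair transcription most in long genes, and this hypothesis was tested over 12185 protein-coding genes. Gene span and log2 fold change at 5 µM had a Spearman rho of -0.034 across genes, with -0.024 and -0.041 in the genes of higher and lower expression, and 0.023 at 2.5 µM. By decile of span, the median at 5 µM went from 0.074 in decile 1 to its lowest, -0.094, in decile 7 and back to -0.003 in decile 10. The shares called down there were 37.5%, 45.5% and 40.2%. Over the whole range longer genes did not fall by more to any useful degree in these data, and genes are not independent replicates.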
